A study of Mus musculus with 4 samples.

How the data were processed

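Libraries were made from total RNA of sorted cells (column-purified with a low-input kit, NEBNext Ultra library kit for Illumina), per the labels' protocols. The submitters' processing notes name STAR, featureCounts, DESeq2 and the mouse build mm10, without versions, settings or roles. Each library has a deposited table of raw counts, whole reads per Ensembl gene, and a second deposited table of normalized signal. The normalized signal was checked against the counts: within each library it equals the counts divided by 1 constant, and the 4 constants (1.05, 1.16, 0.933 and 0.879 for Arc-negative and Arc-positive replicate 1, then replicate 2 in the same order) equal the median-of-ratios size factors that DESeq2 gives for these counts. The raw counts were therefore used for the tests, and the normalized values served 1 alternative. Neither table gives gene names. Gene symbols, positions and exon lengths came from the GENCODE release M21 annotation of GRCm38, the assembly of mm10. It matched 42548 of the 43629 identifiers; the other 1081 held 0.156% of all counts, and 94 of the tested genes were among them. How reads mapping to several places or to overlapping genes were treated, and whether counting used strand, is not given in the sources used here. Levels of genes with near-identical copies, of overlapping genes and of antisense pairs are uncertain for that reason; Gapdh, for example, was at 38.5 CPM in Arc-negative cells and Rpl19 at 2.35 CPM, and both have many processed pseudogenes.

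The depth was 42404264 to 59879755 counts per library. The 10 most abundant genes took 7.55% to 8.45% of a library's counts and mitochondrial genes took 0.817% to 1.10%. Log CPM of the libraries correlated across genes at 0.989 and 0.990 within the groups and at 0.967 to 0.973 between them. Genes are not independent replicates. The common biological coefficient of variation was 0.142, so replicates differed by more than sampling noise. That spread may be technical and does not show that the libraries are independent samples. Each library counted as a sample in the tests. Transcripts of the Y-linked genes Ddx3y and Eif2s3y were present in every library (246 ± 6.40 and 146 ± 2.44 CPM in Arc-negative cells, 262 ± 11.2 and 127.5 ± 4.95 CPM in Arc-positive cells), and Xist was at 0.11, 0.91, 0.20 and 3.24 CPM in Arc-negative replicates 1 and 2 and Arc-positive replicates 1 and 2.

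Groups were taken from the sample titles. The main test was edgeR 4.0.16 in R 4.3.3: TMM scaling, genes kept by filterByExpr by group, a quasi-likelihood fit with group as the only term and 2 residual degrees of freedom, a two-sided F test and Benjamini-Hochberg adjustment over the tested genes, called below 0.05. CPM values use the TMM-scaled library sizes; standard errors are the log2 fold change divided by the root of F. The tested genes held 99.96% of the counts. Before the data were examined, 34 gene lists were fixed, covering dendritic cell subtypes, expression programs, other cell types and RNA quality. Lists with at least 3 tested members (32, the sex-linked list being a sample check only) were compared with all other genes by camera (limma 3.58.1) with a preset correlation of 0.01 and adjusted over lists; members were also adjusted over the list alone. The genes to be named were fixed by rule at the same time. First came Arc, Itgax and the MHC class II genes. Next came the 12 largest log2 fold changes per direction among called genes of the same sign in both same-numbered pairs and at least 10 CPM in the higher group, leaving out predicted models, pseudogenes and antigen receptor segments (415 and 757 genes were eligible). Last came up to 4 called members per list by adjusted p, or the 2 most abundant members of a list with none; 1 gene chosen by this rule is not reported here. Cldn1, Cadm1, Mmp9, Ccr7, Fscn1, Irf8, Batf3, Irf4, Krt10, Krt14, Lyz2, Siglech, Malat1, Cdh5, Lyve1, Gapdh, Rpl19 and Xist, and the genes of the additional observations, were named after their values were seen.

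The scripts were tested on simulated counts with the real means, library sizes and dispersion trend. Changes were given to 200 sampled genes and to the other members of the cholesterol list. Of the calls there, 3.91% were false, and the cholesterol list, changed 1.5-fold, was called while 0 others of 32 were. Simulated genes varied independently, at the trended dispersion, without a replicate-number effect. The simulation therefore does not show how often camera calls an unchanged list whose members vary together. The alternatives were DESeq2 1.42.0, limma-voom, limma-trend on log2 of the authors' normalized signal plus 1, median-of-ratios scaling in edgeR, no filter beyond 1 count, a mean count of at least 50, the replicate number as a block (in edgeR and in DESeq2), an adjusted p below 0.10, an added 2-fold minimum, and each library left out in turn; for the lists, also an estimated correlation and the fry test. Leaving out a library leaves 1 library in a group, and the fit then assumes that it varies like the other group. The filter then also keeps genes with enough counts in only 1 library. With 2 libraries per group no permutation of labels can reach a small p, and none was used.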

Results

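RNA was sequenced from migratory dendritic cells, the antigen-presenting cells that travel from the skin to the lymph node. The cells were sorted from skin-draining lymph nodes of healthy reporter mice in which eGFP marks expression of Arc (also called Arg3.1), a gene best known as an activity-induced gene of neurons. Migratory cells were taken as high in MHC class II and intermediate in CD11c, and were then divided into eGFP-positive (Arc-positive) and eGFP-negative (Arc-negative) cells. Each fraction had 2 libraries, 4 in all. The gene counts summed to 59879755 and 49761285 in Arc-negative replicates 1 and 2, and to 58902648 and 42404264 in Arc-positive replicates 1 and 2. Of 43629 genes listed, 18206 had no count in any library and 15946 were abundant enough to be tested. Levels below are CPM (counts per 1e6 counts of the scaled library size), as mean ± SD with n = 2 libraries per group, and log2 fold changes are Arc-positive over Arc-negative. The labels do not say whether the 2 libraries of a group came from separate animals, so p-values measure only the spread between these libraries, which may be technical.

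The comparison asked how migratory dendritic cells sorted as positive for the Arc reporter differ in their transcripts from those sorted as negative. Arc itself, on chromosome 15 (74669083 to 74672570, build GRCm38), followed the sort. Its level was 574 and 585 CPM in the Arc-negative libraries and 1012 and 1032 CPM in the Arc-positive libraries, a log2 fold change of 0.82 ± 0.10 (SE) with an adjusted p of 0.00424 (edgeR quasi-likelihood test). Arc transcript was therefore abundant in both fractions and 1.76-fold higher in the sorted positives. Because Arc fluorescence defined the groups, this value checks the labels and is not a finding. Genes of the other gate markers were lower in Arc-positive cells. Itgax, which encodes CD11c, fell from 189.9 ± 8.95 to 98.4 ± 3.02 CPM (adjusted p = 0.00254). Among the MHC class II chains, H2-Ab1 (chromosome 17, 34257689 to 34269419) fell from 1878 ± 665 to 408 ± 79.3 CPM, H2-Eb1 from 3408 ± 1208 to 979.7 ± 250.4 CPM and H2-Aa from 3721 ± 1505 to 1260 ± 381 CPM. The wide SDs of the MHC chains reflect higher values in replicate 1 of both groups, and in both same-numbered pairs the Arc-positive library was the lower.

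Of the 15946 genes tested, 953 were higher and 1066 were lower in Arc-positive cells at an adjusted p below 0.05 (edgeR). At least a 2-fold change was seen in 603 of the higher and 476 of the lower genes. The higher genes were mostly sparse transcripts, with a median mean level of 5.63 CPM, whereas the lower genes had a median of 30.4 CPM. Simulated counts had the depth and dispersion trend of these libraries, without spread of genes around that trend. Of the changed genes that passed the filter there, the test recovered 93.7% of those changed 4-fold, 59.4% at 2-fold and 29.2% at 1.5-fold. The 200 sampled genes were changed before filtering, besides 1 gene list, and 15547 genes passed the filter. Recovery in the real libraries may differ. With 1 library left out, and so fewer samples in the fit, both counts were lower in each case: without Arc-negative replicate 1, 623 genes were higher and 737 were lower. Without Arc-positive replicate 2, which alone held abundant salivary gland transcripts such as Bpifa2 (202 CPM, against at most 7.94 CPM elsewhere), 811 were higher and 845 lower.

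**Figure D1:**
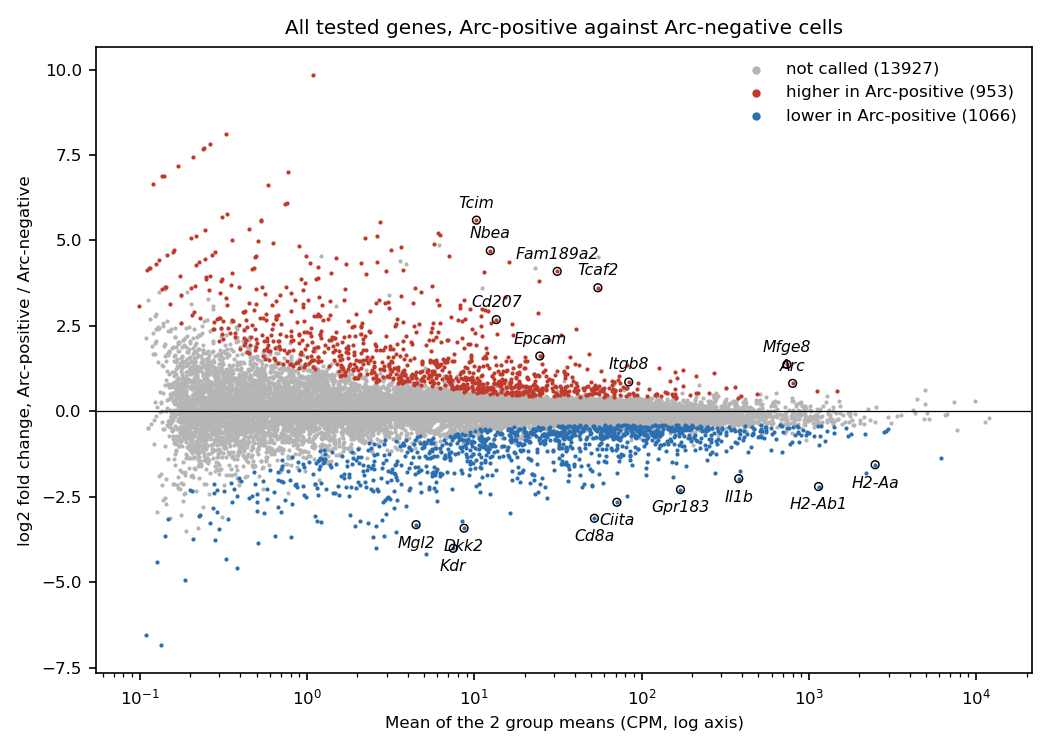
Each point is 1 of the 15946 tested genes, placed by the mean of its group means in CPM (log axis) and by its log2 fold change, Arc-positive over Arc-negative, with genes at an adjusted p below 0.05 in colour and 18 genes named. The 953 higher genes lie mostly at low levels, the 1066 lower genes at higher levels, and fitted fold changes at the far left rest on few counts.

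The 12 largest increases among genes reaching 10 CPM were of genes below 10 CPM in Arc-negative cells. Tcim (chromosome 8, 24437180 to 24438984) rose from 0.42 ± 0.16 to 20.2 ± 5.53 CPM, a log2 fold change of 5.60 ± 0.32 (SE) with an adjusted p of 0.00040. Map2, a microtubule-associated protein of neuronal dendrites, rose from 0.37 ± 0.14 to 11.1 ± 0.78 CPM. Nbea, a membrane-trafficking protein of neurons, rose from 0.93 ± 0.37 to 24.02 ± 2.53 CPM, and Cobl, an actin nucleator, from 0.58 ± 0.20 to 13.5 ± 1.74 CPM. Tjp1, the tight junction scaffold ZO-1, rose from 1.27 ± 0.08 to 21.6 ± 4.10 CPM, and Fblim1, a filamin-binding adaptor of cell adhesions, from 3.21 ± 0.17 to 45.5 ± 4.30 CPM. Pxdn, a peroxidase that crosslinks basement membrane collagen, rose from 1.48 ± 0.75 to 30.6 ± 1.29 CPM. The most abundant of these genes in Arc-positive cells were Tcaf2, which went from 8.26 ± 0.59 to 101.4 ± 10.4 CPM, and Fam189a2, which went from 3.46 ± 0.39 to 59.2 ± 5.98 CPM. Tcerg1l, the protocadherin Pcdh7 and the mineralocorticoid receptor gene Nr3c2 completed the 12, with log2 fold changes of 5.22, 5.16 and 3.67. The highest adjusted p among the 12 was 0.00114, that of Nr3c2.

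The 12 largest decreases were of genes at 10.4 to 139.4 CPM in Arc-negative cells. Kdr, a receptor for VEGF (chromosome 5, 75932827 to 75978458), fell from 14.1 ± 1.11 to 0.87 ± 0.08 CPM, a log2 fold change of -4.01 ± 0.19 (SE) with an adjusted p of 0.00037. Ciita (chromosome 16, 10480059 to 10528418), the transactivator of MHC class II genes, fell from 123.02 ± 7.54 to 19.5 ± 1.11 CPM. Cd8a, which in mice is also made by lymphoid-resident dendritic cells, fell from 93.9 ± 19.9 to 10.7 ± 0.47 CPM. Cd1d1, which presents lipids to NKT cells, fell from 139.4 ± 9.53 to 25.1 ± 1.90 CPM. Btla, an inhibitory receptor, fell from 46.4 ± 0.30 to 8.08 ± 1.06 CPM, and Klri1, a lectin-like receptor of the killer cell family, from 38.97 ± 1.71 to 7.31 ± 0.51 CPM. The Notch ligand gene Dll4 fell from 40.4 ± 10.3 to 7.82 ± 0.38 CPM. Stra6l, a receptor for retinol-binding protein, fell from 29.1 ± 5.72 to 3.65 ± 0.46 CPM. The secreted Wnt modulator Dkk2, the lectins Cd209a and Cd209d and the NMDA receptor subunit gene Grin2c had log2 fold changes of -3.42, -3.22, -2.64 and -2.42. The adjusted p of these 12 genes was at most 0.0114, that of Cd209d. The Cd209, Klri and Cd1d genes have close relatives in the genome, so reads shared between relatives leave their separate levels uncertain.

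Markers of dendritic cell subtypes moved in opposite directions. Langerhans cells are the dendritic cells of the epidermis, and 5 of 5 tested members of their list were higher in Arc-positive cells, also when adjusted over the list alone. Cd207, which encodes langerin (chromosome 6, 83671215 to 83677857), rose from 3.64 ± 0.81 to 23.5 ± 4.13 CPM, a log2 fold change of 2.69 ± 0.21 (SE) with an adjusted p of 0.00082. Epcam rose from 12.1 ± 2.57 to 37.2 ± 0.92 CPM, Cdh1 from 2.13 ± 0.28 to 8.18 ± 0.52 CPM, Mfge8 from 412 ± 13.4 to 1068 ± 95.7 CPM and Cldn1 from 27.0 ± 5.91 to 50.4 ± 10.02 CPM. The list was called higher by camera (adjusted p = 1.83e-12 with a preset correlation, and adjusted p = 0.442 with an estimated correlation). Keratinocyte transcripts were sparse, and the list, with a median of 1.44, was not called. Krt1 rose from 0.05 ± 0.06 to 0.89 ± 0.30 CPM and Trp63 fell from 0.27 ± 0.06 to 0.02 ± 0.004 CPM (adjusted p = 0.0208 and 0.0232, edgeR), while Krt10, at 0.91 ± 0.16 and 1.47 ± 0.57 CPM, and Krt14, at 0.11 ± 0.10 and 0.31 ± 0.12 CPM, were not called. The keratinocyte list was called higher only without Arc-negative replicate 1 (adjusted p = 0.0268, against 0.331 with all libraries). In the list of conventional dendritic cells type 1 (cDC1), 9 of 15 members were lower and 1 was higher, or 10 and 1 adjusted over the list alone. Wdfy4, required by these cells to cross-present antigen, fell from 82.5 ± 20.9 to 18.1 ± 0.82 CPM, and Naaa, Cd36 and Ppt1 had log2 fold changes of -1.83, -1.83 and -1.10. The member that rose was the adhesion molecule gene Cadm1, from 17.2 ± 2.95 to 29.1 ± 2.13 CPM. In the list of conventional dendritic cells type 2 (cDC2), 6 of 14 members were lower and 0 higher, with 7 lower adjusted over the list alone. Sirpa fell from 278.8 ± 17.2 to 92.2 ± 4.61 CPM, Mgl2 from 8.16 ± 4.12 to 0.82 ± 0.11 CPM and Cd300a from 7.12 ± 1.61 to 2.06 ± 0.05 CPM. Camera called both lists lower, cDC1 with an adjusted p of 5.90e-07 and cDC2 with 6.73e-07, and the adjusted p was 0.516 for each with an estimated correlation. The transcription factor genes of these subtypes did not pass the test: Irf8 was at 556 ± 64.9 and 659 ± 1.60 CPM, Batf3 at 300.2 ± 35.5 and 286 ± 39.8 CPM, and Irf4 had a log2 fold change of 0.13, in Arc-negative and Arc-positive cells respectively.

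**Figure D2:**
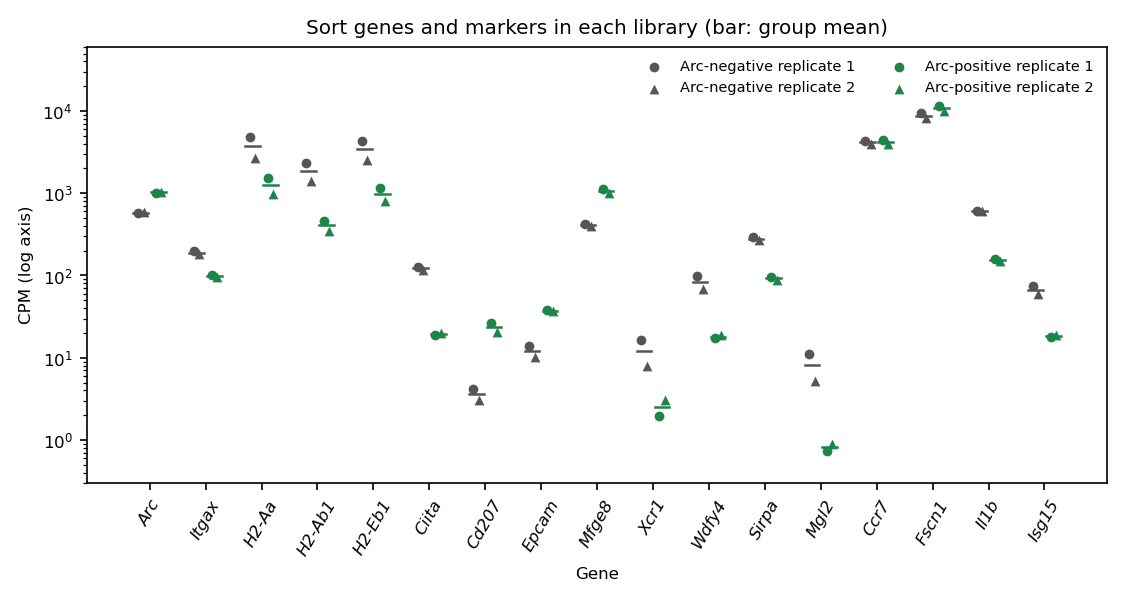
CPM (log axis) of the sort genes and of chosen markers in each of the 4 libraries, with a horizontal bar at each group mean. Cd207, Epcam and Mfge8 lie higher in both Arc-positive libraries, H2-Ab1, Ciita, Wdfy4, Sirpa and Il1b lie lower, and Ccr7 overlaps between the groups.

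Genes of MHC class II presentation were lower as a group. Of 17 tested members, 11 were lower and 0 higher, and adjusted over the list alone 12 were lower and 2 higher. Besides Ciita and H2-Ab1, H2-Ob fell from 19.9 ± 5.91 to 5.48 ± 0.56 CPM and H2-DMb2 from 58.4 ± 19.9 to 14.1 ± 3.86 CPM. Both encode chains of the proteins that control peptide loading. The list was called lower by camera with an adjusted p of 2.45e-10, and with an adjusted p of 0.516 with an estimated correlation it was not. MHC class I presentation was not called (adjusted p = 0.321), and 1 of its 17 members, Nlrc5, the transactivator of MHC class I genes, was lower, as it also was adjusted over the list alone. Nlrc5 fell from 1533 ± 138 to 779 ± 55.3 CPM. Without Arc-negative replicate 2 the MHC class I list was called lower, but this setting leaves unequal shares of the replicate numbers in the groups. The median member was at 528 and 502 CPM in Arc-negative and Arc-positive replicate 1 and at 428 and 434 CPM in replicate 2.

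Interferon-stimulated genes were lower in Arc-positive cells, as were the plasmacytoid dendritic cell, monocyte and heat shock lists (camera, adjusted p = 0.0010, 0.00515 and 0.0215, and 0.496, 0.496 and 0.553 with an estimated correlation). Of 27 members, 13 were lower and 0 higher, and 23 were lower adjusted over the list alone. Isg15 fell from 66.9 ± 9.66 to 18.4 ± 0.94 CPM, Irf7, a transcription factor that amplifies the interferon response, from 36.4 ± 12.1 to 8.93 ± 1.02 CPM, Oasl2 from 29.8 ± 4.52 to 9.11 ± 0.42 CPM and Zbp1 from 60.8 ± 6.66 to 31.4 ± 2.82 CPM. Camera called the list with an adjusted p of 1.83e-12 (adjusted p = 0.442 with an estimated correlation). In the list of inflammatory cytokines and chemokines, 6 of 19 members were lower and 0 higher, or 9 lower and 1 higher adjusted over the list alone. Il1b fell from 607 ± 6.39 to 155.02 ± 5.30 CPM, with a log2 fold change of -1.97 ± 0.10 (SE), and Tnf from 181 ± 4.60 to 69.3 ± 4.76 CPM. The chemokine genes Ccl3 and Cxcl9 fell from 9.56 ± 1.45 to 2.01 ± 0.31 CPM and from 25.7 ± 6.82 to 7.69 ± 0.16 CPM. Camera called this list lower with an adjusted p of 9.85e-07, and the adjusted p was 0.496 with an estimated correlation.

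Ccr7, the receptor that guides dendritic cells to the lymph node, was at 4150.1 ± 281 CPM in Arc-negative and 4231 ± 292 CPM in Arc-positive cells, and Fscn1, an actin-bundling protein of mature dendritic cells, at 8795 ± 784 and 10777 ± 1069 CPM. Neither passed the test (adjusted p = 0.921 and 0.244, edgeR). Other members of the mature migratory program were lower: 8 of 26, with 0 higher, and adjusted over the list alone 10 lower and 1 higher. The costimulatory genes Cd80 and Cd86 fell from 85.8 ± 6.56 to 52.1 ± 0.54 CPM and from 197 ± 20.3 to 117 ± 0.25 CPM. Cd274 (PD-L1) and Pdcd1lg2 (PD-L2), ligands of the inhibitory receptor PD-1, fell from 601 ± 31.9 to 263 ± 13.4 CPM and from 47.3 ± 1.89 to 19.5 ± 0.37 CPM. Camera called the list lower with an adjusted p of 3.07e-05 (adjusted p = 0.442 with an estimated correlation). The list of regulatory mediators went both ways, with 5 of 25 members higher and 6 lower, or 6 and 12 adjusted over the list alone. Itgb8, part of an integrin that activates TGF-beta, rose from 59.6 ± 2.25 to 108.1 ± 0.13 CPM, while Socs3, an inhibitor of cytokine signalling, fell from 107 ± 10.9 to 42.1 ± 3.15 CPM. Cd274 and Pdcd1lg2 belong to this list too. Camera called it lower with an adjusted p of 0.0330, which was 0.496 with an estimated correlation and 0.116 without Arc-positive replicate 2.

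In the NF-kappaB list, 4 of 23 members were lower and 0 higher, or 14 lower and 1 higher adjusted over the list alone. Bcl3 fell from 153.3 ± 2.04 to 92.1 ± 0.18 CPM, Nfkbiz from 517 ± 47.2 to 288 ± 22.3 CPM, Cd40 from 1022 ± 38.2 to 631 ± 0.28 CPM and Icam1 from 1356 ± 10.7 to 1012 ± 46.2 CPM. Camera called the list with an adjusted p of 0.00072 (adjusted p = 0.442 with an estimated correlation). Icam1 lost its call when any library was left out, with adjusted p of 0.133 and 0.108 without Arc-negative replicates 1 and 2, and 0.215 and 0.400 without Arc-positive replicates 1 and 2. Arc is itself an immediate early gene, but the list of immediate early genes was not called (adjusted p = 0.124): 5 of 28 members were lower and 0 higher, or 6 and 3 adjusted over the list alone. Dusp2 fell from 458 ± 14.4 to 224.3 ± 1.004 CPM, Nr4a3 from 1459 ± 137 to 886 ± 111 CPM, Ier3 from 49.5 ± 6.01 to 26.4 ± 3.06 CPM and Egr3 from 8.53 ± 0.81 to 4.27 ± 0.24 CPM. Nr4a3 was not called without Arc-positive replicate 2 (adjusted p = 0.0920). The list of endocytic and synaptic partners of Arc was not called either (adjusted p = 0.690), with 0 of 14 members called by edgeR and 2 higher and 3 lower adjusted over the list alone. Its most abundant members, Dnm2 and Ap2b1, were at 264 ± 19.8 and 233 ± 12.6 CPM in Arc-negative cells and at 242 ± 5.48 and 185 ± 5.24 CPM in Arc-positive cells.

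Chemotactic receptors, integrins and matrix proteases were lower in 17 of 27 members and higher in 1, or in 18 and 2 adjusted over the list alone. Gpr183, a receptor for oxysterols, fell from 284 ± 5.49 to 58.01 ± 2.45 CPM, Ccr6 from 10.8 ± 0.92 to 4.55 ± 0.05 CPM and the hyaluronan receptor gene Cd44 from 1028 ± 74.6 to 555 ± 16.6 CPM. Itgax, described above, is a member. The gene that rose was the protease gene Mmp9, from 0.10 ± 0.01 to 0.73 ± 0.08 CPM. Camera called the list lower with an adjusted p of 1.57e-08 (adjusted p = 0.496 with an estimated correlation). In the list of actomyosin and migration machinery, 9 of 41 members were lower and 3 higher, or 16 and 3 adjusted over the list alone. Cttn, which binds branched actin, rose from 1.14 ± 0.05 to 10.9 ± 0.11 CPM and Mylk, a myosin light chain kinase, from 10.5 ± 0.85 to 26.4 ± 1.44 CPM, while Arpc1b, a subunit of the actin-nucleating complex, fell from 623 ± 27.7 to 371 ± 5.48 CPM and the actin regulator gene Coro1a from 304 ± 69.8 to 145 ± 21.4 CPM. The adjusted p of this list was 0.0157, and 0.608 with an estimated correlation. It was 0.0777 without Arc-negative replicate 1 and 0.116 without Arc-positive replicate 2.

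Genes of cholesterol synthesis and uptake were lower in 4 of 18 members and higher in 0, with 8 lower adjusted over the list alone. Hmgcs1, an early enzyme of the pathway, fell from 259.6 ± 2.96 to 159.7 ± 3.09 CPM, Cyp51 from 224 ± 25.4 to 135 ± 15.2 CPM and Fdps from 52.4 ± 6.40 to 33.8 ± 4.84 CPM. Camera called the list lower with an adjusted p of 8.60e-05 (adjusted p = 0.516 with an estimated correlation). Fdps was not called without Arc-negative replicate 1 (adjusted p = 0.1098) or without Arc-positive replicate 2 (adjusted p = 0.137). The glycolysis and hypoxia list was not called (adjusted p = 0.376). The hexokinase genes Hk2 and Hk1 fell from 22.5 ± 3.21 to 9.31 ± 0.43 CPM and from 81.6 ± 1.36 to 55.8 ± 4.30 CPM, Pfkp fell from 80.02 ± 0.96 to 53.4 ± 0.86 CPM and Bnip3 rose from 3.51 ± 0.15 to 6.04 ± 0.16 CPM. These were the 4 called members of 20, and 3 were lower and 2 higher adjusted over the list alone. Bnip3 lost its call with any library left out (adjusted p of 0.0570 to 0.113), Hk1 without Arc-negative replicate 2 (0.0527) or Arc-positive replicate 2 (0.156) and Pfkp without Arc-positive replicate 1 (0.0774). In the cell cycle list, which was not called (adjusted p = 0.122), 1 of 26 members was lower on either adjustment (all genes, or adjusted over the list alone). This was the proliferation marker Mki67, at 139 ± 7.52 and 73.4 ± 0.70 CPM. Nuclear-encoded oxidative phosphorylation genes were not called as a list (adjusted p = 0.690), and edgeR called 0 of 25 members on either adjustment. Atp5b was at 496 ± 83.7 and 416 ± 55.5 CPM, and Atp5a1 at 351 ± 53.3 and 321 ± 40.2 CPM. Without Arc-negative replicate 2, which leaves unequal shares of the replicate numbers in the groups, the oxidative phosphorylation list was called lower. Its median member was at 51.3 and 48.6 CPM in Arc-negative and Arc-positive replicate 1 and at 40.5 and 42.1 CPM in replicate 2.

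**Figure D3:**
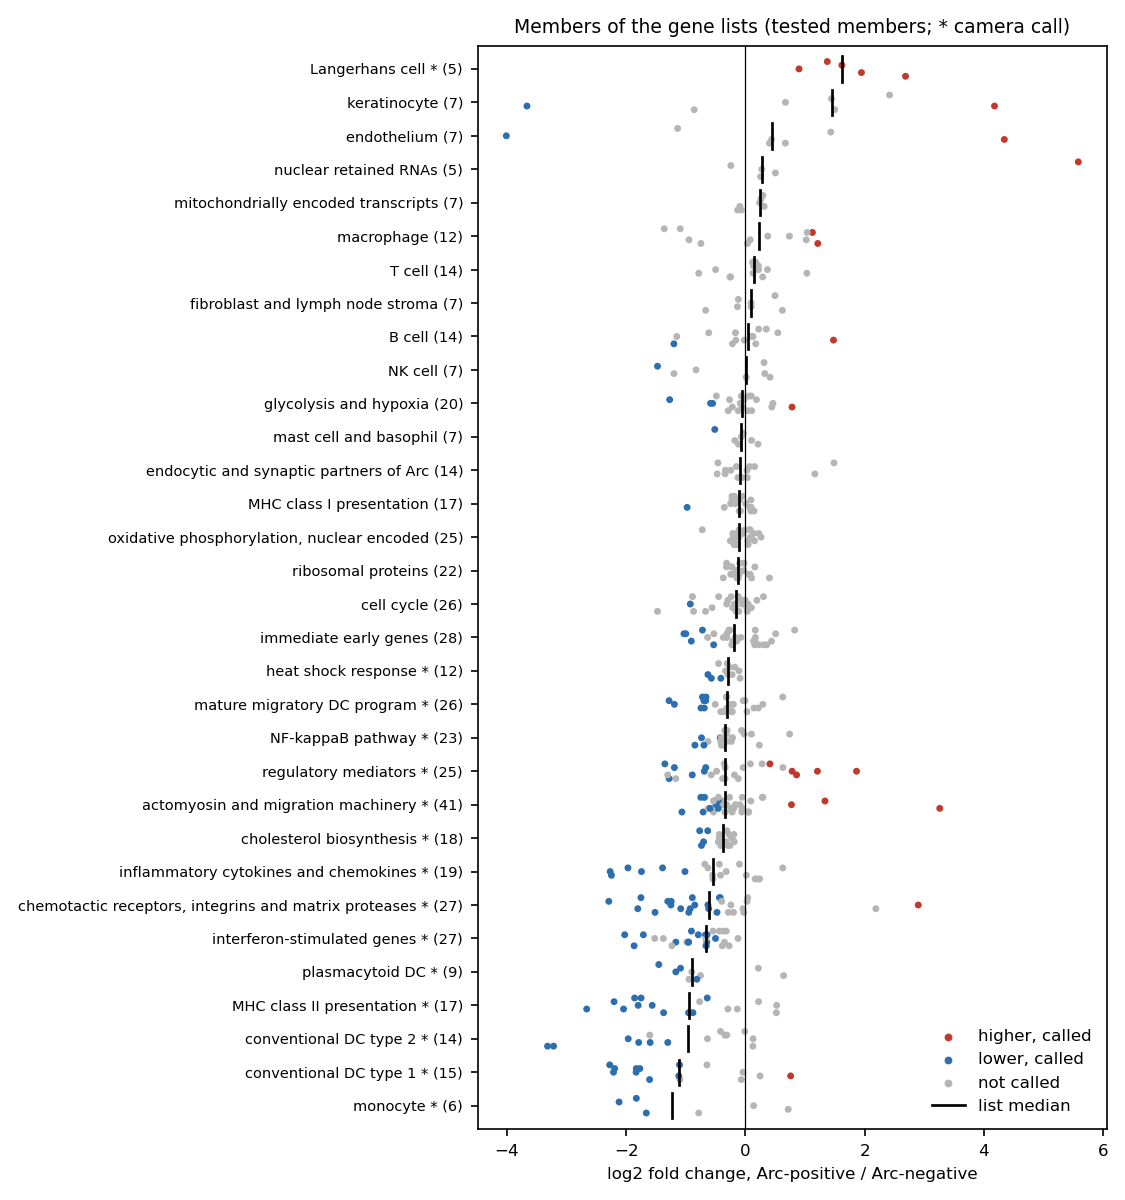
Log2 fold changes, Arc-positive over Arc-negative, of every tested member of the 32 tested gene lists, with the number of tested members in parentheses, a bar at each list median and an asterisk on lists called by camera with its preset correlation. The Langerhans cell list has the highest median, 1.62, and the medians of the monocyte, cDC1, cDC2, MHC class II, plasmacytoid dendritic cell and interferon-stimulated lists lie at or below -0.67.

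Markers of other cell types that the sort could have admitted were mostly sparse. The T cell list was not called (adjusted p = 0.977), edgeR called 0 of 14 members on either adjustment, and its most abundant members, Tcf7 and Il7r, which dendritic cells also make, were at 280 ± 8.73 and 249 ± 34.4 CPM in Arc-negative cells and at 234 ± 7.59 and 176 ± 14.7 CPM in Arc-positive cells. Il7r was called lower without Arc-negative replicate 1 (adjusted p = 0.0267). In the B cell list (adjusted p = 0.977), Cr2 was higher and Cd79b lower among 14 members, on either adjustment, at 2.57 ± 0.002 and 5.56 ± 1.17 CPM in Arc-negative cells and at 7.17 ± 0.08 and 2.42 ± 0.12 CPM in Arc-positive cells. Cd79b was not called without Arc-negative replicate 1 (adjusted p = 0.0651). In the NK cell list (adjusted p = 0.216), 1 of 7 members was lower on either adjustment, Klrk1, from 51.8 ± 8.46 to 18.6 ± 2.83 CPM. The monocyte list was called lower (adjusted p = 0.00515, and 0.496 with an estimated correlation), with 3 of 6 members lower and 0 higher, or 4 and 1 adjusted over the list alone. Plac8, Vcan and Ms4a6c fell from 10.01 ± 4.58, 6.24 ± 0.25 and 5.96 ± 1.16 CPM to 2.82 ± 0.12, 1.96 ± 0.62 and 1.38 ± 0.08 CPM, whereas the abundant myeloid gene Lyz2 had a log2 fold change of 0.14 and was not called. Without Arc-positive replicate 2 the monocyte list lost its call. Its median log2 fold change over the members tested then was -0.37, against -1.22 with all libraries. The plasmacytoid dendritic cell list was called lower (adjusted p = 0.0010, and 0.496 with an estimated correlation), with 4 of 9 members lower, or 5 adjusted over the list alone, and 0 higher. These were Pld4, Tcf4, Runx2 and Spib, from 87.6 ± 13.8, 97.3 ± 6.80, 86.7 ± 12.8 and 194 ± 66.2 CPM to 32.01 ± 2.76, 45.8 ± 6.15, 49.3 ± 2.69 and 86.3 ± 10.2 CPM. Other dendritic cells express these genes as well, and Siglech, a marker of the plasmacytoid type, was at 3.21 ± 0.38 and 5.01 ± 1.54 CPM and was not called.

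The macrophage list was not called (adjusted p = 0.690). Its C1qc and Siglec1 rose from 3.50 ± 1.19 and 1.14 ± 0.11 CPM to 7.63 ± 1.70 and 2.63 ± 0.76 CPM, 2 of 12 members, and adjusted over the list alone 4 were higher and 3 lower. C1qc lost its call without Arc-negative replicate 2 or Arc-positive replicate 1 (adjusted p = 0.0902 and 0.0828), and Siglec1 without Arc-negative replicate 1 or 2 or Arc-positive replicate 1 (0.131, 0.0734 and 0.232). The mast cell and basophil list was not called (adjusted p = 0.690), and its Kit, 1 of 7 members on either adjustment, fell from 33.1 ± 4.04 to 23.2 ± 1.08 CPM. Kit lost its call without Arc-negative replicate 1 and without Arc-positive replicate 1 or 2 (adjusted p = 0.179, 0.200 and 0.0839). The endothelium list was not called (adjusted p = 0.690), with Kdr lower and Prox1 higher among 7 members, or 2 lower and 1 higher adjusted over the list alone. Prox1, a transcription factor of lymphatic endothelium, rose from 0.20 ± 0.13 to 3.98 ± 0.31 CPM, while Cdh5 and Lyve1 were not called. The fibroblast and stroma list was not called (adjusted p = 0.977), edgeR called 0 of 7 members on either adjustment, and Cxcl13 and Col1a2 were at 6.27 ± 0.90 and 1.35 ± 0.15 CPM in Arc-negative cells and at 5.77 ± 1.13 and 1.23 ± 0.06 CPM in Arc-positive cells. In the keratinocyte list (adjusted p = 0.331, and 0.0268 in the higher direction without Arc-negative replicate 1), Krt1 was higher and Trp63 lower among 7 members, or 2 and 1 adjusted over the list alone. Krt1 had 5 and 0 counts in the Arc-negative libraries and 67 and 31 in the Arc-positive libraries. Trp63 had 28 counts over the Arc-negative and 2 over the Arc-positive libraries, a ratio of 14.2 with a 95% interval (exact binomial, counting error only) of 3.59 to 123. Trp63 was not called without Arc-negative replicate 2 or either Arc-positive library (adjusted p = 0.0620, 0.139 and 0.0844). Of the neutrophil list, 2 members were tested, too few for a list test, and Csf3r and Cxcr2 were at 1.57 ± 0.22 and 0.21 ± 0.11 CPM in Arc-negative cells and at 0.92 ± 0.35 and 0.43 ± 0.21 CPM in Arc-positive cells. Without Arc-positive replicate 2 the filter needs enough counts in only 1 library, so further neutrophil members were tested and the list was called higher. Members that pass through the lone Arc-positive library can fix that direction, so this call is no evidence of a difference.

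Malat1 and the median ribosomal protein gene differed more between the replicate numbers than between the groups. Malat1, a nuclear RNA, was at 4446 and 5820 CPM in Arc-negative and Arc-positive replicate 1 and at 8831 and 10242 CPM in replicate 2. The ribosomal protein list was not called (adjusted p = 0.554), with 0 of 22 members called by edgeR on either adjustment. Its median member was at 289 and 262 CPM in Arc-negative and Arc-positive replicate 1 and at 154 and 140 CPM in replicate 2. Rpl4 and Rps3 were at 1254 ± 64.6 and 919 ± 211 CPM in Arc-negative cells and at 1132 ± 13.6 and 783 ± 120.1 CPM in Arc-positive cells. The ribosomal list was called lower without Arc-negative replicate 2 (adjusted p = 0.0172) and without Arc-positive replicate 1 (0.0289), settings that leave unequal shares of the replicate numbers in the groups. Mitochondrially encoded transcripts were not called (adjusted p = 0.567), with 0 of 7 members called by edgeR on either adjustment. Among them, mt-Co1 and mt-Cytb were at 3533 ± 512 and 1350.1 ± 119 CPM in Arc-negative cells and at 3229 ± 278 and 1681 ± 108 CPM in Arc-positive cells. The nuclear retained list was not called (adjusted p = 0.134), and 1 of 5 members, Snhg11, was higher on either adjustment. Snhg11 had 2 counts over the Arc-negative and 109 over the Arc-positive libraries, a ratio of 53.6 with a 95% interval (exact binomial, counting error only) of 14.5 to 448. Without Arc-negative replicate 2 the nuclear retained list was called higher, again with unequal shares of the replicate numbers in the groups. The heat shock list was called lower (adjusted p = 0.0215, and 0.553 with an estimated correlation), with 3 of 12 members lower on either adjustment. Hspa1b, Hspa1a and Hspe1 fell from 1221 ± 68.5, 593 ± 1.28 and 76.1 ± 7.002 CPM to 790.1 ± 49.2, 446 ± 2.44 and 51.3 ± 1.34 CPM, and Hspa1a and Hspa1b are near-identical genes whose separate levels are uncertain. The list call was lost without Arc-negative replicate 1 (adjusted p = 0.204) or Arc-positive replicate 2 (0.130). Hspa1a lost its call with any library left out (0.106 to 0.292), Hspe1 without Arc-negative replicate 1 or either Arc-positive library (0.0667 to 0.0839) and Hspa1b without Arc-positive replicate 1 (0.117).

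Across the 32 lists, 1 was called higher and 14 lower by camera with the preset correlation, after adjustment over the lists. Some called lists share members, so these calls are not independent. Cd40, among others, is in the NF-kappaB and mature migratory lists, and Cd274, among others, in the mature migratory and regulatory lists. With a correlation estimated per list, 0 lists in either direction passed, with 1 higher and 1 lower at an unadjusted p below 0.05 and a smallest adjusted p of 0.442. The fry rotation test called 0 lists higher and 1 lower, with 1 higher and 10 lower unadjusted. The median, the mean and the camera direction differed in sign for the endothelium, NK cell, B cell and Arc partner lists, none of which was called. The list medians were -0.95 for MHC class II, -1.12 for cDC1, -0.97 for cDC2 and -0.67 for interferon-stimulated genes, against 0.007 over all tested genes.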

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

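The genes higher in Arc-positive cells numbered 953 in the main setting and 797 to 966 with DESeq2, limma-voom, limma on the authors' values, median-of-ratios scaling or a mean count of at least 50. The genes lower numbered 1066 and 997 to 1248. With no filter beyond 1 count, which tests 25423 genes, they were 1598 and 1606. At an adjusted p below 0.10 the counts were 1435 and 1523, and with a 2-fold minimum the counts were 603 and 476, by construction. With 1 library left out they were 623 to 811 and 737 to 959, with fewer samples in the fit. Of the 2019 called genes, 1906 were called by DESeq2, 1929 by limma-voom and 1258 to 1433 with 1 library left out, and 0 of these shared calls had the opposite sign. Arc had log2 fold changes of 0.80 to 0.83 in all settings that list genes. Of 101 named genes that were called, 87 kept direction and call in every setting that tested them. The other 14 lost their call in at least 1 setting, and 0 named genes reversed.

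The labels give the groups the same replicate numbers without saying what a number marks. Across genes, the difference between replicates 1 and 2 in Arc-negative cells correlated with that in Arc-positive cells (r = 0.410, and 0.405 after removing a trend on exon length; its rho with exon length was -0.08 and -0.06). With 2 pairs this does not decide whether the numbers pair the samples. With the replicate block, edgeR called 2896 genes higher and 3107 lower, among them all 2019 of the main calls, and 9 named genes not called in the main setting were called: Ap2b1, Atp5b, Tcf7, Il7r, Csf3r, Rpl4, Rps3 and Eif2s3y lower and mt-Cytb higher (7 with the block in DESeq2). Il7r was also called lower with DESeq2, limma on the authors' values, median-of-ratios scaling and no filter. The replicate block with DESeq2 gave 1427 and 2164, and 15 of 15 called lists kept their call with the block. The blocked fit has fewer residual degrees of freedom than the main fit. Arc kept a log2 fold change of 0.82 with the block in edgeR, yet its adjusted p went from 0.00424 to 8.52e-09. It was 1.21e-09 in the edgeR fit with no filter and no block. More calls with the block are therefore not by themselves evidence that the numbers pair the samples.

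Gene lists were more dependent on the test. The lists called higher were 1 in the main setting, 0 with an estimated correlation or with fry, and 1 to 2 with a library left out; the lists called lower were 14, 0 with an estimated correlation, 1 with fry (NF-kappaB, adjusted p = 0.0149) and 10 to 17 with a library left out. The estimated correlation asks how strongly the members vary together over few residual degrees of freedom. It and fry were run only without the replicate block, so differences shared by the replicate numbers enter the residuals they use. The cause of each loss was not tested. Regulatory mediators also lost their call at a mean count of at least 50 (adjusted p = 0.0756). Of simulated genes changed 1.5-fold that passed the filter, 29.2% were recovered.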

Other observations

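The gene families in this and the next paragraph were chosen after the values were seen, so only counts of called members are given. Toll-like receptor genes, which sense microbial products, were lower in Arc-positive cells in 7 of 12 tested members (edgeR) and higher in 0. Tlr1 fell from 35.0 ± 0.47 to 8.15 ± 0.47 CPM, Tlr11 from 56.04 ± 1.21 to 17.3 ± 1.39 CPM, and Tlr5 from 3.76 ± 0.12 to 0.41 ± 0.14 CPM. C-type lectins of the Clec and Cd209 families were lower in 13 of 28 members and higher in 2. Clec7a, the beta-glucan receptor dectin-1, fell from 61.0 ± 11.2 to 23.2 ± 3.33 CPM, whereas Cd209b rose from 0.79 ± 0.07 to 3.98 ± 1.68 CPM. Tlr3, Clec9a, Cd209a and Clec10a are also in the cDC1 or cDC2 lists, so these counts overlap.

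Tight junction genes were higher in 6 of 15 members and lower in 3. Ocln rose from 3.46 ± 0.26 to 16.9 ± 0.77 CPM, beside Tjp1 and Cldn1, the last also in the Langerhans cell list. Cldn9 and Cldn34c1, also higher, reached only 0.60 and 1.59 CPM in Arc-positive cells. Marveld1, the most abundant of the 15, fell from 142 ± 4.78 to 88.1 ± 5.23 CPM, beside the sparse Cldn10 and Cldn13. Integrin subunits were lower in 9 of 26 members and higher in 4, and 6 of the 9 (Itgax, Itgam, Itgal, Itgb1, Itgb2 and Itgav) are also members of the chemotactic receptor list called lower. Itga5 and Itga6, subunits of fibronectin and laminin receptors, fell from 110.2 ± 1.70 to 45.7 ± 2.65 CPM and from 37.6 ± 0.73 to 16.8 ± 0.33 CPM, while Itgb5 and Itgb8 rose from 19.4 ± 1.44 to 41.0 ± 0.56 CPM and from 59.6 ± 2.25 to 108.1 ± 0.13 CPM. Itgav, whose product pairs with those of Itgb5 and Itgb8, fell from 42.7 ± 0.37 to 31.6 ± 1.45 CPM (adjusted p = 0.0423, edgeR).

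The tests of keratinocyte RNA, Langerhans share, scaling, gene length, less mature cells and higher expression in Arc-positive cells were chosen only after the result was seen; those of Langerhans share, gene length and less mature cells each replaced an earlier form, and a test of exon length on the differences between replicate numbers, set beforehand, found a weak trend (rho of -0.08 and -0.06) and was not taken further. Langerhans cell markers were higher in Arc-positive cells, with 5 of 5 members called. Keratinocyte RNA would bring keratins along, but the summed level of Krt5, Krt14, Krt10 and Krt1 was higher by only 1.70 CPM in Arc-positive libraries, against 25.1 CPM for Epcam alone, which argues against it. A candidate explanation is a larger share of Langerhans cells among Arc-positive cells, which would lower cDC1 and cDC2 markers alike. Their medians differed by -0.15, but members spread so widely (larger MAD, 1.09) that this lends the explanation no support; bulk libraries cannot separate a shift in subtype shares from a change within cells, and the list calls did not hold with an estimated correlation, so these cannot be told apart here.

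MHC class II genes were lower in Arc-positive cells, with a list median of -0.95. A scaling difference between libraries would move MHC class I genes as much, but their median was -0.10. A trend on gene length would shift genes of some length by as much, but the medians of 5 equal groups of genes by exon length lay at most 0.0312 from 0, so neither accounts for the change. Less mature dendritic cells in the Arc-negative sort might add MHC class II, cDC1 and cDC2 transcripts together, and the gate on high MHC class II and intermediate CD11c would remove many of them. Between replicates 1 and 2, adjusted for length, the called cDC1 and cDC2 members differed by 0.64 (log2) more in Arc-negative than in Arc-positive libraries. The called MHC class II members differed by 0.21 more. Only the difference of the cDC1 and cDC2 members exceeded the spread of all genes (MAD, 0.23). The explanation needs that of the MHC class II members too. Less mature cells would also lower the mature migratory program in Arc-negative libraries. Of its 26 members, 8 were instead lower in Arc-positive cells and 0 higher, which goes against this explanation for those 8. The other 18, Ccr7 and Fscn1 among them, were not called, and the list call did not hold with an estimated correlation. Medians of chosen genes over 2 libraries per group decide nothing. For the MHC class II genes, less mature cells, a shift in subtype shares and a change within migratory cells therefore cannot be told apart. The shift in shares and the change within cells were not tested on these genes.

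Transcripts abundant in salivary gland stood out in Arc-positive replicate 2 alone: Bpifa2 was at 202 CPM there and at 4.50 to 7.94 CPM in the other 3 libraries, Amy1 at 84.1 against 1.998 to 3.07 CPM, and Smr3a at 39.0 against 1.296 to 2.34 CPM. The 8 such genes first seen summed to 384 CPM, 20.8 times the sum in Arc-positive replicate 1, which argues against expression tied to Arc, and 0 of the 8 were called by edgeR, with adjusted p from 0.0571 to 0.313. Carry-over of salivary gland RNA was the hypothesis tested, and a further 12 salivary genes chosen beforehand summed to 1.65 times the highest other library, below the limit of 2 set beforehand for excluding it. That limit was a poor one, as was seen only afterwards: Lpo and Egf, above 1 CPM in every library, made up 74.9% of that other sum and would hide a small share, and the remaining 10 genes summed to 5.59 against at most 2.12 CPM, mainly Cst10 at 4.25 CPM. These later values are no test of carry-over, which is therefore neither excluded nor shown.

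Serinc2 had no count in either Arc-negative library and stood at 2.16 ± 0.02 CPM in Arc-positive cells.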
